A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

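Total RNA of 4 wild-type and 3 HMT1 deletion cultures was hybridised to Affymetrix Yeast Genome 2.0 arrays, 1 array per culture, and the labels call the cultures biological replicates. The deposited table holds log2 expression values per probe set, which the authors made by RMA (background correction, quantile normalization and median polish over the arrays) with the R package affy 1.52.0, per the submitters' processing notes. The statistical test, the probe set definition and any filter the authors used are not given in the sources used here. RMA sets the distribution of every array alike, so a change in the total amount of messenger RNA cannot be seen, and it compresses differences of dim and of very bright probe sets.

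Array columns were matched to samples by their labels, and the labels' genotype gave the group. Probe sets were named through the platform annotation, with 12 symbols updated through the R64 gene table of RefSeq. Of the 5900 probe sets, 5498 were named to 1 gene each (5449 genes, 47 of them with more than 1 probe set), none to several genes, and 402 had no gene name. Of these 402, 184 were control or reporter probe sets and 218 others, and they stayed out of the comparisons. There were 128 tested probe sets with a suffix for possible matches to several transcripts. No fission yeast probe sets were used here, so the background was taken from 23 control probe sets without a yeast target, and the filter set beforehand on dim probe sets used its fallback, the 25th percentile of all probe set means (8.91). No coordinates are given because the table names no genome build.

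Each probe set was compared between the groups with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without trend or robust option, and p-values were adjusted by Benjamini-Hochberg over the 5498 probe sets with a threshold of 0.05. The errors given for differences are the standard errors of this fit. HMT1 and the list means were also compared by an exact two-sided permutation test over the 35 splits of the 7 arrays into 4 and 3. The 26 gene lists were tested with limma's camera (preset correlation 0.01), with 1 probe set per gene (that with the highest mean), HMT1 left out, and adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Chromosomes were compared by the median difference of their genes against all other chromosomes.

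The design, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named HMT1, up to 12 genes per direction past the test whose groups did not overlap, ranked by size (where fewer than 5 passed, the 5 with the smallest p), all measured PHO regulon genes, and from each other list up to 3 members past the test or else the 1 with the smallest p. A gene named outside it (COS10 and, for the deleted markers, LEU2, MET17 and HIS3) was chosen after its values were seen.

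The procedure was tested on simulated data with 4 and 3 arrays, 5498 probe sets and 200 changed genes in each of 20 draws. It recovered 70.7% of changes of 0.5, 94.8% of changes of 1 and 99.2% of changes of 2 on the log2 scale, with 5.59% false among its calls. With independent genes and a PHO regulon shifted by -0.3, camera and fry each recovered the list in 20 of 20 draws, with 0 and 2 false list calls in all draws. These simulations hold no correlation between genes. Their 200 changed genes also make the adjusted threshold easier to pass than in the data, where 11 probe sets were called. The shares recovered therefore do not carry over to the data. There, 11 probe sets had a measured difference of at least 1, and 4 of them passed, HMT1 included. A planted chromosome shift of 0.5 was measured as 0.51.

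The alternatives were leaving out each array, centring each array on its median, repeating the quantile normalization, leaving out dim probe sets, a replicate block, an intensity trend, a robust fit, array weights, all probe sets, averaging the probe sets of a gene, a fold threshold of 1.5, an adjusted p under 0.01, an ordinary unmoderated test, and leaving out probe sets with the suffixes. Some comparisons were added after the data had been seen. They used only wild-type replicates 2 and 4, only 1 and 3, the reporter signal as a present-or-absent covariate, or probe sets above background controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.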

Results

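Transcript levels of budding yeast, Saccharomyces cerevisiae, were measured on Affymetrix Yeast Genome 2.0 arrays in 4 biological replicates of the wild type and 3 biological replicates of a strain without HMT1, the gene of the main protein arginine methyltransferase of this yeast. The wild type was BY4741, a haploid laboratory strain of mating type a, and the deletion strain carried a KANMX4 cassette in place of HMT1. The labels list rich, phosphate-replete and phosphate-depleted media for the study without saying which of them these cultures grew in. The table held 5900 probe sets, and 5498 of them, named to 5449 genes, were compared. Median log2 expression lay between 9.95 and 9.98 in the 7 arrays. The median standard deviation of a probe set was 0.129 over the 4 wild-type arrays and 0.0714 over the 3 deletion arrays, and the small number of arrays limits the precision of every value below. All differences are deletion minus wild type on the log2 scale.

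HMT1 was at 11.84 ± 0.22 (SD, n = 4) in the wild type and at 4.77 ± 0.26 (SD, n = 3) in the deletion strain. It fell by 7.07 on the log2 scale (SE 0.15, limma adjusted p = 4.89e-07), and all 3 deletion arrays lay below all 4 wild-type arrays. An exact two-sided permutation test of the group means gave p = 0.0286, the smallest value that the 35 possible splits of the arrays allow. The 23 control probe sets without a yeast target had mean levels between 3.34 and 5.13, with a median of 3.85. The upper end of this range, taken as the limit of the background, rests on the control TagH alone. The HMT1 signal of the deletion strain was within the range, and HMT1 was at least 104-fold lower there. The other marker genes named in the strain's genotype did not separate the groups. URA3, LEU2 and MET17 had wild-type levels of 3.55, 5.01 and 4.05 and deletion levels of 3.66, 4.99 and 4.06. HIS3, of which the his3Δ1 allele keeps a part, was at 11.52 and 11.53.

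Besides HMT1, 4 genes rose and 5 genes fell in the deletion strain. The acid phosphatase genes PHO11 and PHO5 fell by 1.06 (SE 0.13) and 1.05 (SE 0.14), to levels of 12.19 ± 0.20 and 11.94 ± 0.14 (SD, n = 3) from 13.26 ± 0.20 and 12.99 ± 0.25 (SD, n = 4). YCL049C fell by 0.88 (SE 0.10), SWI1, a subunit of the SWI/SNF chromatin remodeller, by 0.76 (SE 0.10), and SIZ1, a SUMO ligase, by 0.52 (SE 0.07). HOP1, a protein of the meiotic chromosome axis, rose by 0.98 (SE 0.11) from a low wild-type level of 5.88, and GAS2, a glucan-modifying enzyme made in sporulating cells, rose by 0.75 (SE 0.09). YNL040W rose by 0.47 (SE 0.06).

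The fourth gene that rose, YLL066W-B, has 3 probe sets, and they differed. The 2 probe sets whose suffix marks a possible match to several transcripts rose by 1.06 (SE 0.11) and 0.80 (SE 0.09), while the probe set without the suffix was 0.06 higher (SE 0.11, limma adjusted p = 0.905), at a wild-type level of 5.48 near the background. The PHO11 probe set carries such a suffix as well, and PHO12, its close relative, was not measured by a named probe set here. AQY1, a water channel, was 0.54 higher (SE 0.10) and did not pass the test (limma adjusted p = 0.150).

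The test behind these names called 11 of the 5498 probe sets at a limma adjusted p under 0.05, 5 higher and 6 lower, with adjusted p between 0.0246 and 0.0494 for all but HMT1. At an unadjusted p under 0.05 there were 365 probe sets, where chance alone gives 274.9. In 420 probe sets (7.64%) the values of the groups did not overlap, against 5.71% by chance. HMT1 alone passed without wild-type replicate 4, without deletion replicate 1, without deletion replicate 2 or without deletion replicate 3 (1 probe set each). Without wild-type replicate 3, 3 probe sets passed, 2 of them among the 11 (HMT1 and YCL049C). Without wild-type replicate 1, 9 passed, 6 of them among the 11, and without wild-type replicate 2, 8 passed, 5 of them among the 11. PHO11 passed in none of these fits, and PHO5 only without wild-type replicate 1.

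**Figure D1:**
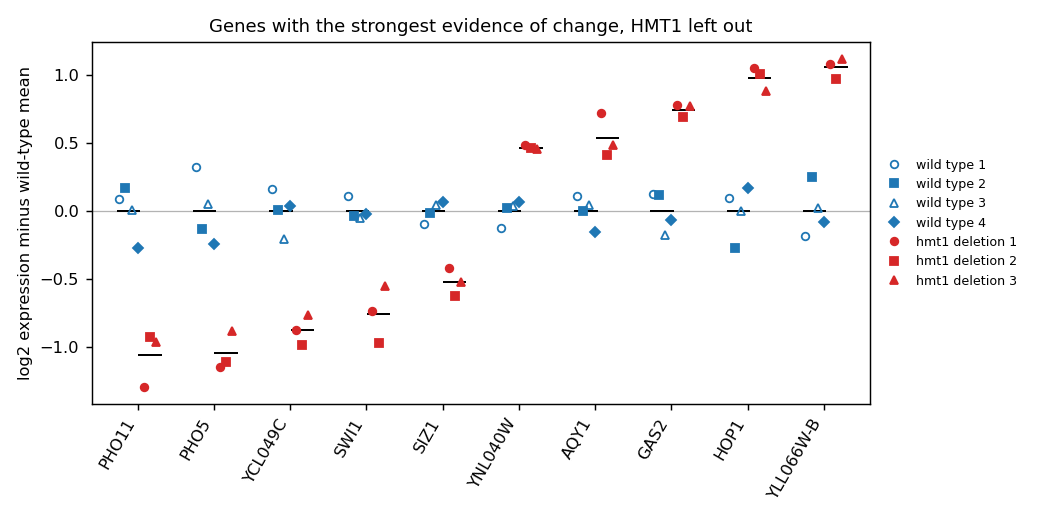
Log2 expression of the genes with the smallest p in each direction, HMT1 left out, in each array after subtracting the gene's wild-type mean (vertical axis). Open and filled blue symbols are the 4 wild-type arrays, red symbols the 3 deletion arrays, and black bars the group means. For each gene the deletion arrays lie on one side of the wild-type arrays, from PHO11 at -1.06 to YLL066W-B at 1.06, and AQY1 (0.54) did not pass the test.

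The study's title names phosphate-associated genes, and the first group of genes compared was the PHO regulon. It holds targets of the transcription factor Pho4, many but not all of which serve phosphate uptake and storage. Of its 20 measured members, 19 were lower in the deletion strain and 1, PHM7, was 0.33 higher. The median difference was -0.22 and the mean -0.34. In 14 members, all of them lower in the deletion strain, the arrays of the groups did not overlap (70.0%, against 5.71% by chance). PHO5 and PHO11 passed the test over all probe sets. Adjusted over the list alone, 8 members passed, all lower: PHO5, PHO11, PHM6, PHO89, CTF19, SPL2, PHO8 and GDE1. Because the series' title reports phosphate genes from these samples, the list is not independent evidence of its direction.

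Among these 8 genes the differences from the wild type were spread widely. PHM6 was at -0.90 (SE 0.13) and PHO89, the sodium-dependent phosphate transporter, at -0.95 (SE 0.22). Smaller differences were measured for CTF19 at -0.40 (SE 0.09), SPL2, a regulator of low-affinity phosphate transport, at -0.36 (SE 0.11), PHO8, the vacuolar alkaline phosphatase, at -0.32 (SE 0.08), and GDE1, which cleaves glycerophosphocholine, at -0.28 (SE 0.08). The 4 measured genes of the polyphosphate-making VTC complex, VTC1 to VTC4, lay between -0.15 and -0.05 and did not pass over the list or over all probe sets. PHO84, the high-affinity phosphate transporter, was at -0.11 (SE 0.06), with a wild-type level of 14.06 close to the highest values on any array (14.63). PHO81, the inhibitor of the Pho80-Pho85 kinase, was at -0.23 (SE 0.10), and its wild-type replicate 2 stood above the other 3 wild-type arrays.

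The list as a whole was called lower by camera with its preset correlation of 0.01 (adjusted p = 8.61e-14 over 26 lists), but not with an estimated correlation (adjusted p = 0.115, unadjusted p = 0.0044). The rotation test fry, which asks whether the members move one way without comparing them with other genes, called it lower (adjusted p = 0.0106, and 0.00152 for change in either direction). The mean of the 20 genes was 11.25 ± 0.06 (SD, n = 4) in the wild type and 10.91 ± 0.02 (SD, n = 3) in the deletion strain (exact permutation p = 0.0286, the smallest possible, at which a single list cannot pass an adjustment over the 26 lists). A second list, of phosphate signalling and low-affinity transport, had a median of -0.0069 over 15 genes and was not called (adjusted p = 0.692), with IPK1, an inositol phosphate kinase, at -0.40 (SE 0.10).

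**Figure D2:**
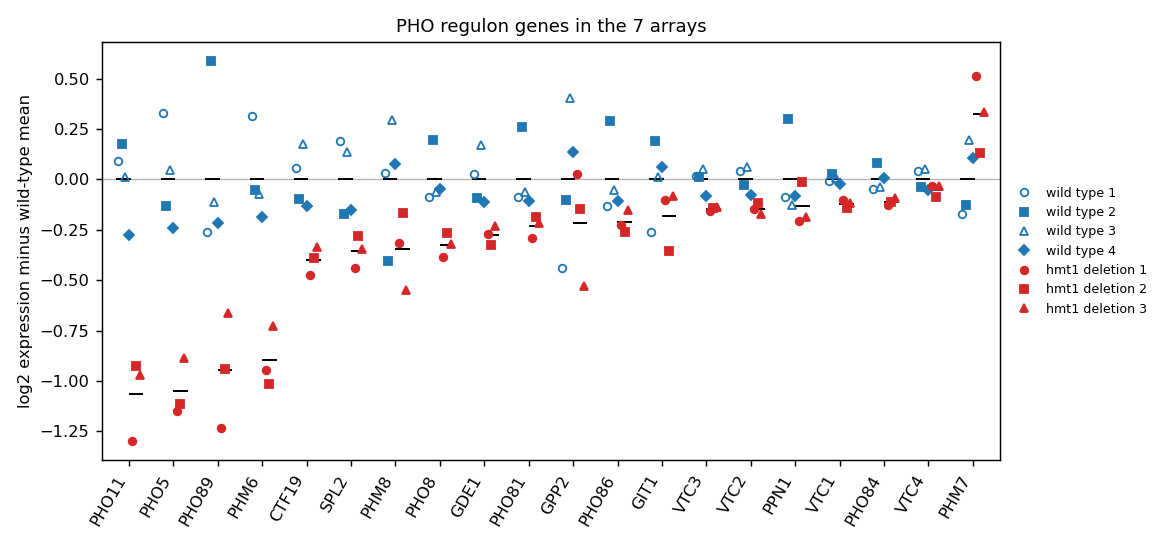
Log2 expression of the 20 measured PHO regulon genes in each array after subtracting the gene's wild-type mean (vertical axis), ordered by the difference between the groups. Blue symbols are the 4 wild-type arrays, red symbols the 3 deletion arrays, and black bars the group means. The differences run from -1.06 for PHO11 to 0.33 for PHM7.

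A further 25 lists of genes were compared to see which other processes differed between the strains, and camera with the preset correlation called 8 of them. None of the 8 held with an estimated correlation (adjusted p = 0.911 to 0.919), and fry called none of them for change in one direction. The exact permutation test of the list means gave unadjusted p from 0.0571 to 1 over the 25 lists, with 0.171 for the TCA cycle list and 0.0571 for the PAU family. Genes of the TCA cycle and the respiratory chain were higher as a group, with 46 of 46 members higher, a median of 0.15 (adjusted p = 8.30e-11) and COX5A at 0.25 (SE 0.07). Seripauperins and related cell wall genes (the PAU family) were lower as a group, with 16 of 19 members lower and a median of -0.34 (adjusted p = 3.53e-08). Adjusted over the list alone, 7 PAU genes passed, among them PAU8 at -0.42 (SE 0.09), and fry gave an adjusted p of 0.0472 for change in either direction and 0.566 for change in one direction. The PAU genes are near-identical to each other, so the signal of 1 of them can come from another. Among the 26 lists, only the PHO regulon, the TCA cycle and the PAU family were called with the preset correlation whichever array was left out.

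The 6 other called lists lost their call when certain arrays were left out. Stress-induced genes had a median of 0.24, with 42 of 46 members higher (adjusted p = 1.50e-05) and GSY1, a glycogen synthase, at 0.77 (SE 0.24). The call ended without wild-type replicate 1 (adjusted p = 0.107) or deletion replicate 2 (0.0509). Genes of sulfate assimilation and methionine synthesis had a median of 0.068, with 29 of 30 higher (adjusted p = 0.00827), and lost the call without the same arrays (adjusted p = 0.164 and 0.0827). Ribosome biogenesis genes had a median of -0.067, with 79 of 96 lower (adjusted p = 0.00175), which ended without wild-type replicate 1 (0.862), wild-type replicate 4 (0.177) or deletion replicate 2 (0.980). Zinc-regulated genes had a median of -0.18, with 14 of 15 lower (adjusted p = 0.00548), which ended without wild-type replicate 2 (0.0772) or deletion replicate 2 (0.111). Purine synthesis genes had a median of -0.057, with 16 of 18 lower (adjusted p = 0.0486), and the call ended without wild-type replicates 3 (0.113) or 4 (0.839) or deletion replicates 1 (0.0671) or 2 (0.251). In that list IMD2, an IMP dehydrogenase, was at -1.42 (SE 0.23), passed over the list alone and did not pass over all probe sets (limma adjusted p = 0.131). The IMD2 probe set carries a suffix for a possible match to several transcripts. Iron-regulated genes had a median of -0.14, with 24 of 30 lower (adjusted p = 0.0126), which ended without wild-type replicate 1 (0.154), wild-type replicate 3 (0.236) or deletion replicate 2 (0.307). Without deletion replicate 2, 3 lists were called in place of 9.

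**Figure D3:**
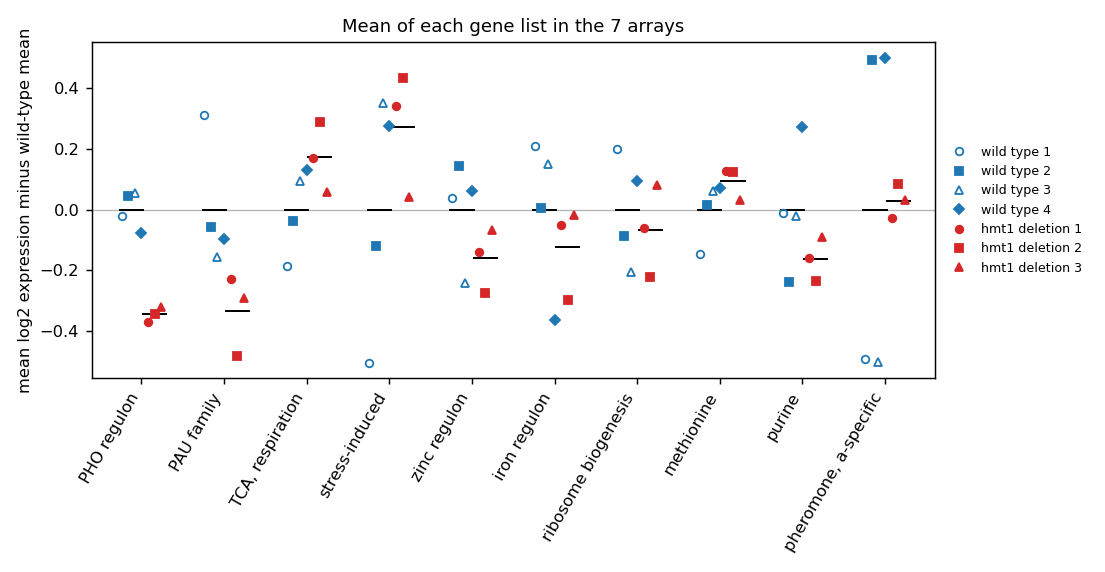
Mean log2 expression of the 9 called gene lists and of the pheromone list in each array after subtracting the list's wild-type mean (vertical axis). Blue symbols are the 4 wild-type arrays (replicates 1 and 3 open, 2 and 4 filled), red symbols the 3 deletion arrays, and black bars the group means. The PHO regulon arrays of the groups are apart, while the pheromone list separates wild-type replicates 2 and 4 from 1 and 3 with the deletion arrays between them.

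The other 17 lists were not called. Meiosis and sporulation genes, markers of another cell type, had 19 members higher and 21 lower, with a median of -0.026, a mean of 0.019 and a lower direction in camera (adjusted p = 0.869), while fry called change in either direction (adjusted p = 9.96e-05). HOP1 and GAS2 were the 2 members past the test, over all probe sets and over the list alone. The alpha-specific genes, markers of the opposite mating type, had a median of -0.015 (adjusted p = 0.692). In the subtelomeric COS family, with a median of -0.071 (adjusted p = 0.151), COS8 at -1.01 (SE 0.25) and COS10 at -0.38 (SE 0.10) passed over the list alone. The ergosterol genes had a median of 0.036, a mean of -0.0084 and a lower direction in camera (adjusted p = 0.869). Known Hmt1 substrates had a median of -0.042 (adjusted p = 0.218) and the 3 other arginine methyltransferase genes a median of 0.060 (adjusted p = 0.425). Cytosolic and mitochondrial ribosomal protein genes had medians of 0.0069 (adjusted p = 0.828) and 0.017 (0.467). Glycolysis genes had a median of 0.0031 (0.828), hexose transporters -0.035 (0.164), with HXT1 at -0.44 (SE 0.15), phospholipid synthesis genes -0.051 (0.0730) and core histones 0.037 (0.337). Gcn4-dependent amino acid genes had a median of 0.044 (adjusted p = 0.389), pheromone response and a-specific genes 0.091 (0.425), the 3 measured neighbours of HMT1 -0.055 (0.869) and the 4 auxotrophic markers 0.013 (0.675).

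The wild-type arrays did not form a uniform group. The 5 J01347 reporter probe sets, which are named to no gene here, read 3.18 to 4.44 in wild-type replicates 1 and 3 and 6.16 to 12.6 in the other 5 arrays. Pheromone response and a-specific genes followed this division: 26 of 27 were higher in wild-type replicates 2 and 4 than in 1 and 3, with a median difference of 0.51 between the pairs. Against replicates 2 and 4 the deletion strain had a pheromone list median of -0.23 (adjusted p = 6.21e-12, preset correlation), and against replicates 1 and 3 a median of 0.40 (adjusted p = 3.24e-33). Neither held with an estimated correlation (adjusted p = 0.308 and 0.139). The iron list had medians of 0.014 and -0.25 against the same pairs, the Gcn4 list 0.13 and -0.069, and the COS family -0.24 and 0.049. Camera with the preset correlation called the Gcn4 list higher against replicates 2 and 4 (adjusted p = 4.04e-06) and lower against 1 and 3 (2.61e-06). It called the COS family lower against replicates 2 and 4 (0.00144). These calls did not hold with an estimated correlation (Gcn4 0.843 and 0.317, COS 0.836). The PHO regulon was lower against both pairs, with medians of -0.24 and -0.20, as were the PAU genes (-0.24 and -0.32). The TCA cycle genes were higher against both (0.11 and 0.20). With an estimated correlation, camera called none of these lists against either pair (PHO regulon adjusted p = 0.732 and 0.198). In camera with the preset correlation, the calls of the sulfate (adjusted p = 0.319) and iron (0.718) lists ended against replicates 2 and 4. Those of the zinc (0.615) and ribosome biogenesis (0.0765) lists ended against replicates 1 and 3. The purine call ended against both pairs (0.112 and 0.0610). The zinc list had medians of -0.28 and -0.055. Against replicates 2 and 4 alone 11 probe sets passed, 2 of them shared with the comparison over all arrays (HMT1 and YCL049C). Against replicates 1 and 3 alone 7 passed, 4 of them shared. PHO5 and PHO11 passed against neither pair.

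Gains or losses of a whole chromosome were looked for as a shift of all its genes. The 16 chromosomes lay within 0.028 of the rest of the genome, and no array deviated by more than 0.029. None passed the exact permutation test (smallest adjusted p = 0.457), and 1, chromosome IX, had an unadjusted exact p under 0.05 (0.0286, shift -0.015). A single chromosome could not have passed, since the smallest possible p of 0.0286 becomes 0.457 when adjusted over 16 chromosomes.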

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

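The tests of other splits for the gene lists and for the PHO regulon, of the stress covariate and of the rescalings were chosen before their results were seen; the test of other splits for the number of probe sets, those on brightness, on the wild-type pairs and on YLL066W-B were chosen afterwards. Of the 35 splits of the 7 arrays into 4 and 3, 1, the real one, gave as many as 11 probe sets. The highest other number was 1. This is the smallest share that 35 splits allow, and the count includes HMT1, the deleted gene. It argues against chance as the source of the count but does not exclude it. The count itself falls to 1, HMT1, without wild-type replicate 4 or any 1 deletion array, and 5 other splits gave more probe sets than the real 365 at an unadjusted p under 0.05, up to 996. The number of called gene lists is different: 15 of the 35 splits gave as many as the real 9, the highest other number being 12. For this number the splits give nothing against chance.

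The PHO regulon was lower in the deletion strain, and 1 of the 35 splits, the real one, gave a fry p as small (0.000407, the smallest other 0.011). By the size of the median, 2 of the 35 splits were as extreme. Wild-type replicates 2, 3 and 4 against the rest gave 0.23 and the real split -0.22. The rest in that split was wild-type replicate 1 with all deletion arrays, so the split carries much of the strain difference. Its positive sign also means higher values in wild-type arrays. The division of wild-type replicates 1 and 3 from 2 and 4 is argued against as the source of the shift. The median was -0.20 against the pair with the smaller difference. Other differences within the wild type were not tested. Against a stress state stands an upper 95% bound of -0.21 for the shift of -0.34, with the stress list mean as a covariate. Against a bias that follows brightness stands a median of 0.0093 over the 100 genes nearest in brightness to each member. Other effects of the normalization stay open, because rescaling the arrays moved the median of all genes by under 0.01 and so tested little (PHO median -0.21 or lower). An effect of the HMT1 deletion, other differences between the strains and culture conditions that the labels do not give also stay open and untested.

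By the reporter probe sets, the wild-type arrays fell into pairs. The 5 J01347 reporter probe sets were higher, as a mean of the other 5 arrays over the mean of wild-type replicates 1 and 3, by 3.14 (1_at), 4.74 (1_s_at), 8.54 (2_at), 7.38 (3_at) and 8.20 (4_at), and the U46493 reporter by 6.64; replicates 1 and 3 read within the background, which leaves lower bounds of 1.22, 3.11, 7.25, 6.57, 7.27 and 5.01. Hybridization is argued against by its spike-in controls, whose median difference between replicates 2 and 4 and replicates 1 and 3 was -0.19, and a dilution of the a cells by cells of the opposite mating type in replicates 1 and 3 by an alpha-specific median difference of 0.030, with MF(ALPHA)1 between 3.95 and 4.14 in the 7 arrays. A stock of cells without the sequence that the reporters detect stays open: all 5 lay at or below the highest background control in both arrays and above it in the other 5, but this observation prompted the explanation and does not test it. Diploid cells and the labelling step were not tested, and the design gives no biological group for the pairs.

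YLL066W-B was called higher through probe sets that may match several transcripts. Signal from near-identical copies elsewhere in the genome was not told apart from a change of YLL066W-B itself. The probe set without the suffix differed by 0.061, from a wild-type level of 5.48. A suffixed probe set about as dim, at 5.72, rose by 0.80, so a low level alone need not hide a rise. A single probe set near the background does not decide the question. No biological explanation was tested.

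Probe sets without a gene name also separated the strains. Probe set 1778286_at was 1.54 higher in the deletion strain, from 6.79 to 8.33, and 1778724_x_at was 1.39 higher, from 7.18 to 8.57. The reporter AJ002682-1_s_at was 10.2 higher as measured, from 3.62 in the wild type, within the background, to 13.83, or at least 8.70 higher, and the sources used here do not name its target.

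In 8 of 79 genes and list means tested, 1 wild-type array stood apart from the other 3, measured as its gap to the nearest array divided by the range; chance alone gives 3.95. In replicate 2 the ratio was 0.864 for PHO8, 0.882 for PHO81 and 0.890 for PPN1, all higher there than in the other 3, and 0.942 for the glycolysis list mean (lower) and 0.961 for the phospholipid list mean (higher). In replicate 1 it was 0.833 for SWI1 (higher). In replicate 3 it was 0.861 for RRP36 (lower) and 0.894 for the mean of the HMT1 neighbours (higher).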

How the results depend on the processing

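The comparisons restricted to one wild-type pair, with the J01347 signal as a covariate and with a filter at the background controls were chosen after seeing the data. The covariate marked whether an array's J01347 signal was above the background, as in all but wild-type replicates 1 and 3. The difference it gives is that against replicates 2 and 4, with another error, so it is no separate check. HMT1 stayed past the test in each alternative that gave it a value (-7.20 to -6.93); it has none without dim probe sets, being below that level. The count of 11 probe sets ranged from 1 to 9 when 1 array was left out. It was 6 without dim probe sets, 59 (22 higher, 37 lower) with array weights, 5 with the probe sets of a gene averaged, 1 at an adjusted p under 0.01, 1 with an ordinary unmoderated test, 4 without the suffixed probe sets, 7 against wild-type replicates 1 and 3 and 5 with the covariate; fewer arrays or probe sets enter some of these, and for the rest the cause was not tested. It was 9 to 14 under the others. Against wild-type replicates 2 and 4 the 11 calls were 2 higher and 9 lower. With the replicate block the count was 1, HMT1. Same-numbered arrays did not deviate together (correlations -0.035, 0.17 and -0.51, against -0.30 to 0.36 for unlike numbers). This gives no sign that the numbers pair the arrays, but so few arrays cannot exclude a pairing. The 9 called lists became 3 to 10 with 1 array left out, 0 with an estimated correlation (PHO regulon adjusted p = 0.115) and 1 with fry. Of the lists called over all arrays only the iron list turned direction, uncalled, against replicates 2 and 4 (adjusted p = 0.718) and with the covariate (0.730). Lists uncalled over all arrays also turned: against replicates 2 and 4 the pheromone list, called lower there (6.21e-12), and ergosterol (0.647); with the covariate the same lists (4.66e-12 and 0.601); against replicates 1 and 3 the Gcn4 list, called lower there (2.61e-06), and, uncalled, COS and YRF1 (0.484), glycolysis (0.615), meiosis (0.713), hexose transporters (0.910) and cytosolic ribosomal proteins (0.955); meiosis with quantile normalization (0.936), fry (0.887) and the replicate block (0.960), the last also for cytosolic ribosomal proteins (0.960). With 1 array left out, lists that turned at least once, uncalled when they did, had adjusted p of 0.0372 to 0.902 (cytosolic ribosomal proteins), 0.0859 to 0.941 (mitochondrial ribosomal proteins), 0.591 to 0.990 (glycolysis), 0.0232 to 0.565 (Gcn4), 0.565 to 0.980 (ergosterol), 0.00148 to 0.921 (pheromone), 0.827 to 0.997 (HMT1 neighbours), 0.307 to 0.766 (auxotrophic markers) and 0.375 to 0.997 (meiosis). With an estimated correlation, camera called neither the pheromone list against replicates 2 and 4 (adjusted p = 0.308) nor the Gcn4 list against 1 and 3 (0.317). The causes were not tested. No chromosome passed in any alternative, where a single one hardly can. Of 923 values for 52 named genes, 824 kept direction and call, 91 lost the call, 8 gained one and 0 turned round. All 91 losses came from the 9 genes other than HMT1 that were called over all arrays. Most named genes were uncalled there and had no call to lose. The 824 therefore do not measure how stable the calls were. For the lists the same counts were 342, 45, 19 and 32 of 438. Rescaling moved the median of all genes by under 0.01. Background controls reached 5.13; URA3, MET17 and LEU2 lay below that in both groups, and HOP1 and YLL066W-B not far above it.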

Other observations

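All values in this part were chosen after they were seen. Several genes differed by more than 1 on the log2 scale without passing the test over all arrays. FRE7, a metal reductase, was 2.12 higher in the deletion strain (SE 0.55, limma adjusted p = 0.414). It belongs to the genes controlled by the copper-sensing factor Mac1, and the other genes of that group looked at were CTR1 at 0.80 (SE 0.40), FRE1 at 0.74 (SE 0.43), REE1 at 0.64 (SE 0.28) and IRC7 at 0.27 (SE 0.19), none past the test over all arrays. Their differences depended on the wild-type pair: against wild-type replicates 2 and 4, CTR1 and FRE1 were 1.45 and 1.43 higher, and against replicates 1 and 3 they were 0.15 and 0.054 higher. FRE7 was higher against both pairs, by 2.87 and 1.38. On the lower side, YHR214C-E was at -1.57 (SE 0.28, limma adjusted p = 0.150), DAN1, a cell wall mannoprotein of anaerobic cells, at -1.43 (SE 0.59, 0.742), OPT2, an oligopeptide transporter, at -1.23 (SE 0.26, 0.264) and YMR317W at -1.06 (SE 0.39, 0.719). Some of these genes passed under other settings: FRE7, REE1 and OPT2 against wild-type replicates 2 and 4 alone, FRE7, OPT2 and YHR214C-E with array weights, OPT2 without wild-type replicate 1, YHR214C-E without wild-type replicate 2 and REE1 without wild-type replicate 3.

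Between the wild-type pairs, 6 probe sets passed at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 242, fewer than the 274.9 that chance alone gives. The mating genes FIG1, PRM6, PRM2 and AGA1 were higher in replicates 2 and 4 by at least 3.06, 2.97 and 1.56 (the first 3, within the background in replicates 1 and 3) and by 2.19, and YGR109W-A of the Ty3 retrotransposon by 2.80. The arginine synthesis gene ARG3 was at -1.80 in the same comparison, and ARG1 at -2.57 without passing (adjusted p = 0.138). In 25 of the 27 pheromone and a-specific genes both arrays of replicates 2 and 4 lay above both of replicates 1 and 3, while 35.8% of all genes had the pairs apart in either direction, where chance gives 33.3%. The deletion mean lay between the pair means for 24 of the 27 genes, against 39.4% of all genes. FIG1, for example, was at 8.20 in replicates 2 and 4, at 4.84, within the background, in replicates 1 and 3 and at 6.03 ± 0.19 (SD, n = 3) in the deletion strain.

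Some other splits of the 7 arrays gave more probe sets at an unadjusted p under 0.05 than the real 365: 5 of the 35 did, up to 996 for wild-type replicates 1, 2 and 4 against wild-type replicate 3 and the deletion arrays.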
